A study of Mus musculus with 2 samples.

How the data were processed

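Poly(A) RNA from mouse primary B-lineage cells was sequenced in 2 libraries, 1 from untreated cells and 1 from cells treated for 18 h with estradiol to induce the transcription factor C/EBPα. The groups were taken from the labels. The name of the estradiol library's deposited file carries 18 h, as its label does, and the abbreviation EOH, which the labels do not explain, while the untreated library's file name carries UT. Every fold given here rests on the labels being right. Per the labels' protocols, B cell precursors of the pro-B and pre-B stages were taken from bone marrow by magnetic sorting for CD19 and cultured with IL-7. The protocols are the same text for both libraries and do not say which steps each went through. They name OP9, a stromal cell line used as a feeder layer for reprogramming cultures, and a flow cytometric sort that removed feeders and dead cells. The libraries were made with a stranded mRNA kit, per the labels' protocols.

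Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.3.0.1, HTSeq and DESeq were used with the genome build mm9. Their roles, the gene annotation and the strand setting of the counting are not given in the sources used here. Each deposited file holds a gene name and a signal value, and no header. The deposited signal is a normalised read count: the authors divided each library's reads per gene by 1 size factor, as the tool names in the labels and the values show. In both files 100% of the values were whole multiples of the smallest positive value, within a tolerance of 0.001 reads. The multiples were taken as reads, and the inverse of the step, which is the size factor, was 0.982 for the untreated and 1.02 for the estradiol library. The reads used here were recovered from the deposited values in this way.

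The rows for reads outside any gene and for ambiguous reads were left out of totals and comparisons. Reads outside genes were 24.6% of all listed reads in the untreated and 21.4% in the estradiol library, and ambiguous reads were 0.321% and 0.242%. The remaining 18099 genes held 53218554 reads in the untreated and 54601044 reads in the estradiol library. No listed gene was at 0 in both libraries, 1682 were at 0 in the untreated library and 551 in the estradiol library. A count of 0 allows up to 3 reads, which is a deposited value of 3.05 in the untreated and 2.95 in the estradiol library.

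Each group has 1 library, so there is no replicate check on any difference, and no p-value is given. The quasi-likelihood test of edgeR 4.0.16 was attempted on the recovered reads and could not be fitted, because 0 residual degrees of freedom remained. It therefore gave no calls. For single genes the fold is the ratio of the deposited values, with an exact Clopper-Pearson 95% interval of the ratio given the summed reads of both libraries. These intervals cover counting error only, not the variation between cultures or animals. PCR copies are not independent molecules, so the true counting error is wider. For counts of genes and for gene lists, the log2 fold was computed as log2 of the estradiol value plus 1 over the untreated value plus 1, which understates the fold of low genes. Genes with a mean value of 20 or more over both libraries were called measured. A measured gene was counted as higher or lower when this fold reached 2 in either direction.

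Before the data were examined, 36 gene lists were fixed for lineages, pathways and other cell types. The median log2 fold of each list's measured members was placed among 10000 random lists of the same size, matched on mean value in 20 bins. A list was said to stand apart when its percentile was below 2.5 or above 97.5. This describes these 2 libraries and is not a test across replicates. Of the 963 distinct genes looked for, fixed and added lists together, 7 were matched through an alternative name in RefSeq's table for GRCm38.p6, among them Spi1 as Sfpi1, and 48 were not matched. The mitochondrially encoded genes, 13 in number, were not matched in the files used and were not analysed here. Because that table's assembly is not mm9, no coordinates are given. After the data were examined, 4 further lists were added: genes shared by leukocytes, Y-linked genes, adipocyte genes and imprinted genes.

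The genes named in the text were chosen by a rule fixed at the same time as the lists. It takes the 10 highest and the 10 lowest folds among genes with a mean of 50 or more, leaving out predicted genes, pseudogenes, antisense genes, small RNAs and receptor gene segments. It adds 15 fixed genes, the 2 highest and 2 lowest members of each list, and the 5 highest values in each library. Other named genes are said to be chosen after their values were seen.

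On simulated reads for this comparison, drawn for all 18099 genes with 100 genes changed 4-fold and 100 changed 1.5-fold, 100% of the former and 1.0% of the latter were called. Of the unchanged measured genes 0.038% were called, and 95.5% of the counting intervals held the true ratio. These reads were drawn with counting error alone (Poisson), so the rates leave out variation between cultures or animals. Of 200 random lists of 25 genes, 4.5% stood apart, and 100% of the lists raised 4-fold did. Alternatives were other pseudocounts, filters, fold thresholds and scalings, among them the trimmed mean of M values of edgeR, and for lists the mean of the members and 10 bins. Scaling to the pan-leukocyte genes was added after the data were examined. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3.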

Results

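Gene expression was compared between untreated mouse primary B cells and primary B cells treated with estradiol for 18 h, with 1 RNA-seq library per group. The question was which transcripts differ once estradiol has been given to induce C/EBPα, a transcription factor of the myeloid lineage. The untreated library held 53218554 reads in genes and the estradiol library 54601044. Values are the deposited normalised read counts. With 1 library per group no difference has a replicate check, and the 95% counting intervals given with single genes cover counting error only. The groups are those of the labels, and the deposited file of the estradiol library is named with the abbreviation EOH, which the labels do not explain. If its label were wrong, the folds would be those of another condition.

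Of 13365 measured genes, 3324 (24.9%) were at least 2-fold higher and 2283 (17.1%) at least 2-fold lower in the estradiol library, while 7758 lay between. B lineage genes, neutrophil and basophil genes and cell cycle genes were among the lower ones, and matrix and stromal genes were among the higher ones. The 5 highest values in the untreated library belonged to Hsp90ab1, Eef2, Serinc3, B2m and Tubb5, among them genes of protein folding, translation, antigen presentation and microtubules. In the estradiol library they belonged to Fn1 (fibronectin), Spp1 (osteopontin), Vim (vimentin), Bgn (biglycan) and Col6a1 (a collagen VI chain). Fn1 was 13.3-fold higher (95% counting interval 13.2 to 13.4) and Spp1 18.4-fold higher (18.2 to 18.6), and both were present in untreated cells at 62287 and 23503. Vim was 4.55-fold, Bgn 9.60-fold and Col6a1 8.71-fold higher. Hsp90ab1 was 1.57-fold lower, Eef2 1.19-fold lower, B2m 1.55-fold lower, Serinc3 2.38-fold lower and Tubb5 2.19-fold lower. After scaling to genes shared by leukocytes of many lineages (pan-leukocyte genes), a choice made after the data were seen that multiplies the estradiol values by 2.98, 9606 genes were at least 2-fold higher and 563 at least 2-fold lower, so the share of higher genes among both went from 59.3% to 94.5%. Under that scaling a gene given here as less than 2.98-fold lower lies above its untreated level, as those 5 genes do, along with Btk, Csf1r, Lyz2, Myc, Tgfb1 and Tgfb3.

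B lineage transcripts were lower in the estradiol library. All 27 measured members of the B cell identity list were at least 2-fold lower, with a median of 11.2-fold, below all 10000 matched random lists. Pax5, the transcription factor that maintains B cell commitment, went from 7546 to 548, which is 13.8-fold lower (12.6 to 15.0). Cd19, the surface protein by which the cells were isolated, was 8.66-fold lower (8.43 to 8.91), from 47924 to 5532, and Ebf1, another B cell transcription factor, was 4.09-fold lower (3.94 to 4.24). The lowest folds of the list belonged to Fcrla, 30.1-fold lower (21.3 to 44.0), and Fcer2a, which had 47 reads in untreated and 1 in estradiol cells, a ratio of 48.7 with an interval of 8.33 to 1964. Btk, a kinase of the B cell receptor pathway, and Ikzf1, a lymphoid transcription factor, were nearest to their untreated levels, at 2.68-fold and 3.08-fold lower.

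Among the pro-B and pre-B stage genes, 16 of 22 were at least 2-fold lower and 2 at least 2-fold higher, with a median of 7.56-fold lower, below all random lists. Rag1, a subunit of the V(D)J recombinase, was 32.1-fold lower (26.0 to 40.0), and Arpp21 was 21.1-fold lower. Flt3 and Mme, a growth factor receptor and a membrane peptidase, were 5.78-fold and 4.12-fold higher. Of 20 B cell receptor signalling genes, 15 were at least 2-fold lower, among them Card11 (15.5-fold) and Blnk (13.4-fold), whereas Bcl10 (1.03-fold higher, 0.973 to 1.08) and Lyn (1.11-fold lower, 1.07 to 1.14) were close to their untreated levels. The list's median was 3.07-fold lower, below all random lists. In the same libraries the pan-leukocyte genes, a list made after the data were seen that shares 3 genes with the B cell and myeloid lists, had a median of 2.98-fold lower over 29 genes, with 22 at least 2-fold lower and 2 at least 2-fold higher. Stromal markers had a median of 9.60-fold higher.

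**Figure D1:**
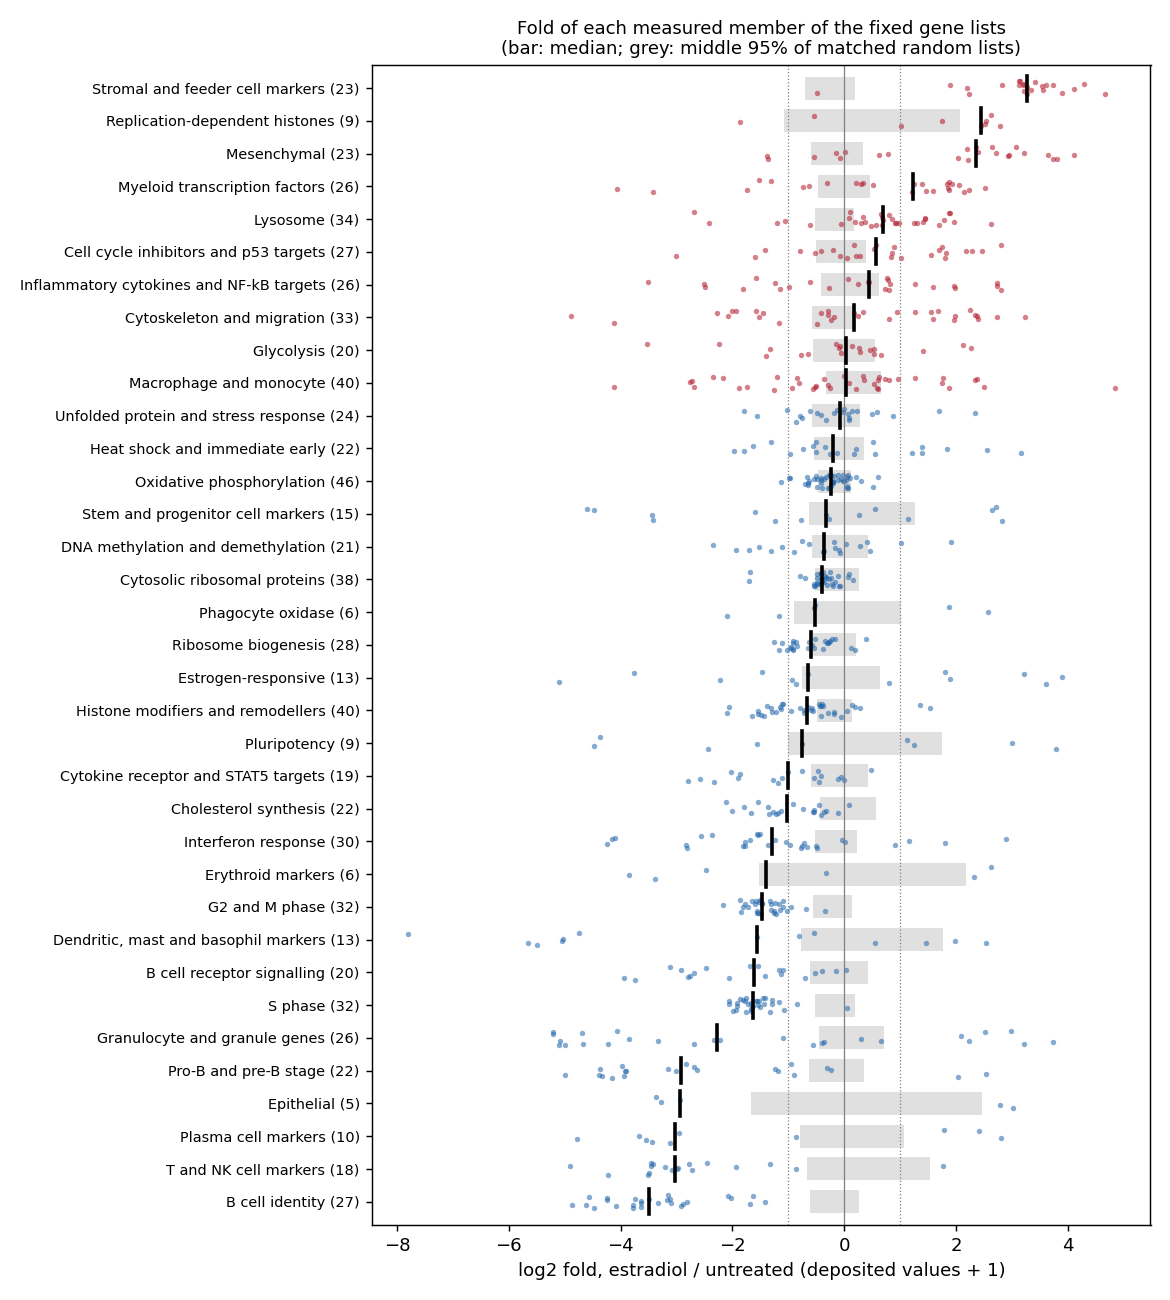
Log2 fold between the estradiol and the untreated library (x axis, deposited values plus 1) for each measured member of 35 gene lists (y axis, number of members in brackets); points are genes, coloured red where the list's median is above 0 and blue where it is below, black bars are medians, dotted lines mark 2-fold, and grey bands hold the middle 95% of matched random lists. The stromal list has the highest median (3.26) and the B cell identity list the lowest (-3.49), both outside their grey bands.

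Myeloid transcripts differed in both directions, in libraries where stromal markers were 9.60-fold higher and pan-leukocyte genes 2.98-fold lower. Cebpa, the gene whose product the treatment was meant to induce, was present in both libraries, at 6510 in untreated and 7534 in estradiol cells, a ratio of 1.16 (1.12 to 1.20). The labels do not say whether the untreated cells carried the inducible C/EBPα, nor whether its transcript is counted under Cebpa. The ratio of Cebpa therefore does not show whether C/EBPα was induced. Cebpb, a related factor, was 4.40-fold higher (4.12 to 4.71), and Sfpi1, which encodes the myeloid and B cell factor PU.1, was 1.26-fold higher (1.20 to 1.32). Among 26 myeloid transcription factors, 14 were at least 2-fold higher and 5 at least 2-fold lower, and the median, 2.35-fold higher, lay above all random lists. Fosl2, an AP-1 subunit, was 5.75-fold higher and Id1, an inhibitor of helix-loop-helix factors, 4.68-fold higher. Cebpe, a factor of late granulocyte maturation, was 19.9-fold lower (8.24 to 62.7), from 96 to 5 reads, and Gfi1b was 11.0-fold lower. With the mean of the members in place of the median, this list no longer stood apart, with a mean log2 fold of 0.49. No library of stromal cells alone was used here. The higher folds of this list therefore do not tell expression in leukocytes apart from stromal RNA.

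The macrophage and monocyte list did not stand apart: 8 of 40 members were at least 2-fold higher and 10 at least 2-fold lower, and its median lay at percentile 37.3. Itgam, the integrin chain CD11b, was 17.5-fold lower (14.5 to 21.2), from 2025 to 116, and Mrc1, the mannose receptor, was 6.78-fold lower. Csf1r, the receptor for macrophage colony-stimulating factor, was 1.47-fold lower (1.32 to 1.64), and Lyz2, which encodes lysozyme, was 1.19-fold lower (1.13 to 1.24). Cd33, a sialic acid receptor of myeloid cells, was 5.65-fold higher (5.21 to 6.14). Cx3cr1, a chemokine receptor, had 1 read in untreated and 58 in estradiol cells, a ratio of 56.0 with an interval of 9.66 to 2248.

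Granulocyte genes split. Of 26 measured members, 15 were at least 2-fold lower and 6 at least 2-fold higher, and the median, 4.86-fold lower, lay below all random lists, with a mean log2 fold of -1.63 against the median of -2.28. Ngp, a neutrophil granule protein, was 37.0-fold lower (33.1 to 41.6), S100a9, a calcium-binding protein of neutrophils, 36.9-fold lower (33.7 to 40.5), and Ltf, lactoferrin, 34.4-fold lower (30.1 to 39.6). Mmp8, neutrophil collagenase, was 13.3-fold higher (12.3 to 14.4), and Prtn3, the primary granule protease proteinase 3, was 9.33-fold higher (8.56 to 10.2). The NADPH oxidase subunits split as well: Ncf1 was 5.93-fold and Cybb 3.66-fold higher, whereas Rac2 was 4.27-fold and Ncf4 2.24-fold lower, and the list of 6 did not stand apart, at percentile 15.1. Among the dendritic, mast and basophil markers, 7 of 13 were at least 2-fold lower and 3 at least 2-fold higher, and the list stood apart at percentile 0.135, with a median of 2.93-fold lower that became 0.02 (log2) after scaling to pan-leukocyte genes. The list still stood apart under that scaling. With a minimum mean of 100 that list's median log2 fold was -3.15, and the mean of its members was -2.32. Fcer1a, a chain of the IgE receptor, had 219 reads in untreated and 0 in estradiol cells, which is at least 75.7-fold lower against a floor of 3 reads, while the exact interval, which also covers the error of the untreated count, begins at 61.0-fold. The basophil protease gene Mcpt8 was 51.3-fold lower (38.6 to 69.8), and Prss34, another protease gene, 80.1-fold lower (56.3 to 118). Flt3 and Zbtb46, which dendritic cells express, were 5.78-fold and 4.03-fold higher.

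**Figure D2:**
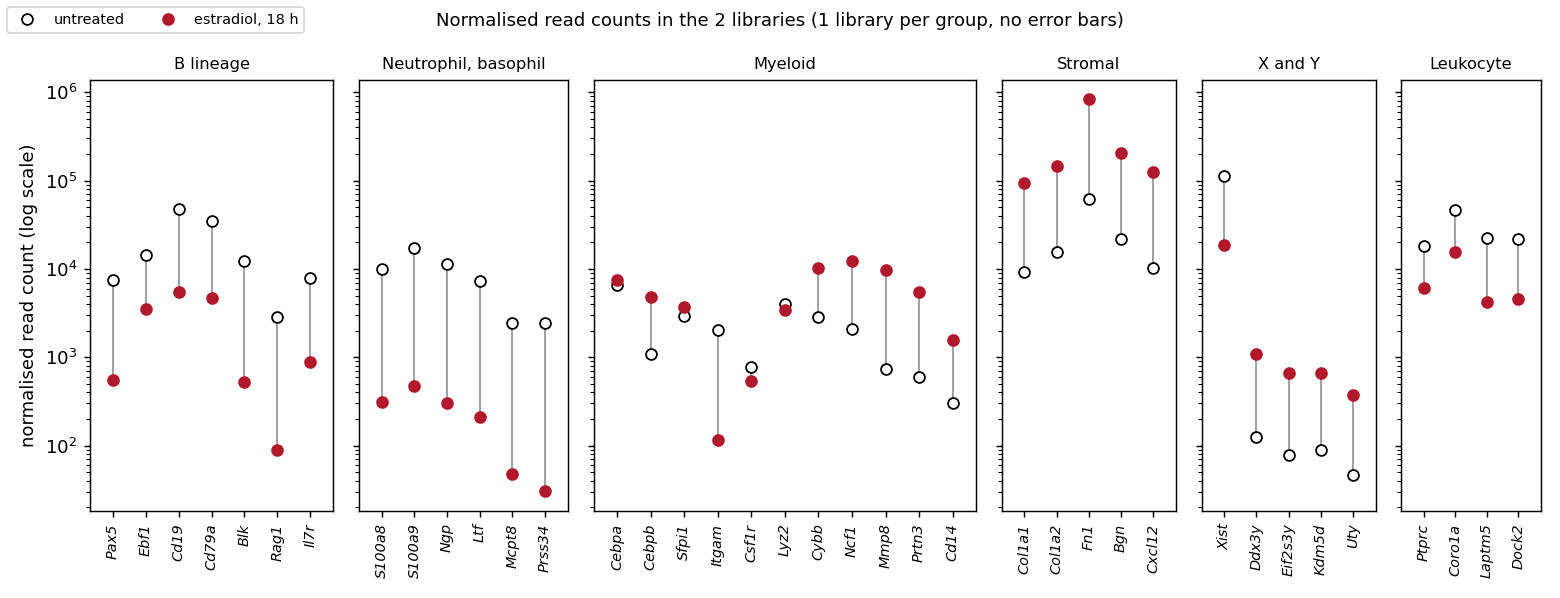
Normalised read counts (y axis, log scale) of single genes (x axis) in the untreated library (open circles) and the library after 18 h of estradiol (filled circles), grouped by lineage; each point is 1 library, so there are no error bars, and the genes shown that the text does not name were chosen after their values were seen. The B lineage, neutrophil, basophil and leukocyte genes shown were lower with estradiol, the stromal and Y-linked genes shown were higher, as with Fn1 at 62287 and 829872, Xist was lower, and the myeloid genes went both ways.

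Markers of other cell types differed between the libraries. Of 23 measured stromal and feeder cell markers, 22 were at least 2-fold higher in the estradiol library and none was 2-fold lower, with a median of 9.60-fold, above all random lists. Tagln, an actin-binding protein of contractile cells, was 25.3-fold higher (23.1 to 27.8) and Ctgf, a matrix-associated growth factor, 19.7-fold higher (18.3 to 21.1), while Vcam1 was 3.73-fold higher and Thy1 1.40-fold lower. A sort to remove feeder cells is part of the labels' protocol. The untreated library also held these transcripts, and 20 of the 23 had a value of 1000 or more there. Xist, expressed from the inactive X chromosome of female cells, was 6.01-fold lower (5.92 to 6.10), from 111363 to 18528, and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were 8.56-, 8.62-, 7.99- and 7.52-fold higher; these 5 genes were chosen after their values were seen. The strand setting of the counting is not given, so reads from Tsix, antisense to Xist, cannot be told apart from those of Xist. T and NK cell markers were lower, with 16 of 18 members at least 2-fold lower and a median of 8.20-fold, below all random lists (log2 -3.04, or -2.27 with a pseudocount of 10). Cd2 was 32.1-fold and the kinase Lck 18.7-fold lower, Cd4 was 1.82-fold lower, and Gata3 was 3.44-fold higher.

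Plasma cell markers had a median of 8.18-fold lower, below all random lists, with 6 of 10 at least 2-fold lower, such as Slamf7 (27.5-fold) and Igj (13.3-fold), and 3 at least 2-fold higher, such as Fkbp11 (6.96-fold) and Sdc1 (5.29-fold). The mean log2 fold of the plasma cell markers was -1.54, against the median of -3.03. Erythroid markers did not stand apart, at percentile 3.45 with 3 of 6 lower and 2 higher; Car2 was 10.5-fold lower, Gata1 went from 41 to 2 reads, a ratio of 21.2 (5.52 to 181), and Epor and Spta1 were 6.66-fold and 5.19-fold higher. Stem and progenitor cell markers did not stand apart, at percentile 13.5, with 4 of 15 higher and 6 lower. Slamf1 and Mycn were 27.5-fold and 22.5-fold lower, and Mecom and Hoxa10 were 7.12-fold and 6.62-fold higher.

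Among pluripotency genes, 9 of the 30 list members were measured, some of which other cells also express, with 4 at least 2-fold higher and 4 at least 2-fold lower, and the list did not stand apart, at percentile 5.78. Pou5f1, which encodes Oct4, had 22 reads in untreated and 4 in estradiol cells, and Sox2 had 21 and 2 reads; both had a mean below 20. Nanog had 6 and 57 reads, a ratio of 9.17 (3.96 to 26.0), in libraries where stromal markers were 9.60-fold higher. Klf4, a reprogramming factor that myeloid cells also express, was 2.37-fold higher (2.26 to 2.48), from 2611 to 6189, and Myc was 1.70-fold lower (1.65 to 1.75). Tbx3 was 15.9-fold higher (7.06 to 44.4) from 6 reads, and Lin28a went from 39 to 1 read, a ratio of 40.4 with an interval of 6.84 to 1637.

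Genes of the mesenchymal list were higher: 15 of 23 were at least 2-fold higher and 2 at least 2-fold lower, and the median, 5.14-fold higher, lay above all random lists. Serpine1, an inhibitor of plasminogen activation, was 17.3-fold higher (16.2 to 18.4) and Snai1, a repressor of epithelial genes, 14.1-fold higher (12.3 to 16.3), while Tgfb1 and Tgfb3 were 2.61-fold and 2.56-fold lower. Without the 2 genes shared with the stromal list, 13 of 21 were at least 2-fold higher, and the stromal markers were higher by 9.60-fold in the same library. These values therefore do not tell a change within the B cells apart from stromal RNA. Of the epithelial genes only 5 were measured; Cldn4 (12.7-fold) and Epcam (10.1-fold) were lower, and Krt19 (9.46-fold) and Tjp1 (6.89-fold) were higher. Their median of 7.64-fold lower stood apart at percentile 0.23, but not with a minimum mean of 5 or with the mean of the members.

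Genes of DNA methylation and demethylation did not stand apart as a list, at percentile 14.0, with 6 of 21 at least 2-fold lower and 2 at least 2-fold higher. Tet2, which oxidises 5-methylcytosine, went from 3196 to 3900, a ratio of 1.22 (1.16 to 1.28). Uhrf1, a cofactor of maintenance methylation, was 5.11-fold lower and Apobec3 3.85-fold lower, while Idh1 was 3.77-fold and Gadd45a 2.03-fold higher. Among histone modifiers and remodellers, 15 of 40 were at least 2-fold lower and 2 at least 2-fold higher, with a median of 1.59-fold lower at percentile 0.12 that turned to 0.90 (log2) above 0 after scaling to pan-leukocyte genes. The list still stood apart under that scaling. Ezh2, the methyltransferase of Polycomb repressive complexes, was 4.29-fold lower and the remodelling ATPase Smarca4 4.16-fold lower, whereas its paralog Smarca2 was 2.91-fold and the demethylase Kdm5b 2.54-fold higher.

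Cell cycle genes were lower. In the S phase list 30 of 32 genes were at least 2-fold lower, with a median of 3.11-fold, and in the G2 and M phase list 29 of 32, with a median of 2.78-fold; both medians lay below all random lists. Mki67, a marker of cycling cells, was 4.49-fold lower (4.43 to 4.54), Top2a 3.63-fold, and Ung, a member of the S phase list, 4.15-fold, while Cdc6, which loads the replicative helicase, went from 6409 to 1526. E2f1 (1.04-fold higher, 0.993 to 1.08), Gins2 (3289 and 1824), Anln (1.27-fold lower) and Aurka (1.60-fold lower) differed least. The medians were close to the 2.98-fold of the pan-leukocyte genes, and after scaling to those genes the G2 and M phase median was 0.10 (log2) above 0. Both lists still stood apart under that scaling. Cell cycle inhibitors and p53 targets had a median of 1.49-fold higher at percentile 99.5, with 10 of 27 at least 2-fold higher and 3 at least 2-fold lower, and did not stand apart with the mean of the members. Cdkn2b, an inhibitor of cyclin D kinases, was 7.01-fold and the p53 target Phlda3 5.55-fold higher, and Perp (9.85-fold) and Rbl1 (3.03-fold) were lower. Replication-dependent histone transcripts had a median of 5.47-fold higher over 9 genes, 7 of them at least 2-fold higher, at percentile 99.6; Hist1h4h (7.51-fold) and Hist2h3c1 (6.22-fold) were highest, and Hist1h1a (3.89-fold lower) and Hist1h4i (1.47-fold lower) were lowest. With a minimum mean of 5 that median was -0.38 (log2) and the list did not stand apart, nor did it with the mean of the members. Only 9 of the 22 list members were measured in these poly(A) libraries, and near-identical histone copies can share reads. These values are therefore uncertain and are not taken as a measure of S phase.

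Growth and metabolic lists had medians nearer to 0, in libraries where pan-leukocyte genes were 2.98-fold lower and stromal markers 9.60-fold higher. Ribosome biogenesis genes had a median of 1.52-fold lower at percentile 1.43, with 4 of 28 at least 2-fold lower, such as Ncl (2.38-fold) and Wdr43 (2.25-fold), while Polr1a and Nop2 were 1.31-fold and 1.14-fold higher. Cholesterol synthesis genes had a median of 2.03-fold lower, below all random lists, with 11 of 22 at least 2-fold lower, among them Idi1 (4.51-fold) and Stard4 (4.03-fold); Mvk (1.08-fold lower, 0.985 to 1.18) and Tm7sf2 (1.06-fold higher, 0.888 to 1.26) did not differ beyond counting error. After scaling to pan-leukocyte genes these medians were 0.97 and 0.55 (log2) above 0, and both lists still stood apart. Lysosome genes had a median of 1.61-fold higher at percentile 99.98, with 11 of 34 at least 2-fold higher and 4 at least 2-fold lower; Cd63 (6.19-fold) and Ctsl (3.89-fold) were highest, and Ctss (6.46-fold) and Laptm5 (5.33-fold), which leukocytes express, were lowest. Ribosomal protein genes (2 of 38 lower, Rps18 3.27-fold and Rpl3 3.21-fold lower, Rpl23 and Rps6 1.11-fold and 1.06-fold higher) stayed within the range of random lists, at percentile 11.2, and their processed pseudogenes can share reads, so these values are uncertain. So did oxidative phosphorylation genes (1 of 46 lower, Sdhb 2.19-fold and Ndufs8 1.99-fold lower, Cycs 1.53-fold and Cox8a 1.44-fold higher) at percentile 39.3. Glycolysis genes (3 of 20 higher, 4 lower) lay at percentile 66.5, with Aldoc going from 236 to 19.6, Slc2a3 4.77-fold lower, and Ldhb and Eno2 4.82-fold and 4.39-fold higher.

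Of the signalling lists, those for interferon response and STAT5 targets were lower, beside the same stromal and pan-leukocyte medians. Interferon-stimulated genes had a median of 2.46-fold lower, below all random lists, with 17 of 30 at least 2-fold lower and 3 at least 2-fold higher. Oasl1 and Oas3, of the family of oligoadenylate synthetases, were 18.9-fold and 17.7-fold lower, and the membrane proteins Ifitm6 and Ifitm1 were 7.52-fold and 3.48-fold higher. Cytokine receptor and STAT5 target genes had a median of 2.00-fold lower at percentile 0.03, with 9 of 19 at least 2-fold lower and none 2-fold higher; Il2rg, the shared chain of the IL-7 receptor, was 6.97-fold and Ccnd3 5.96-fold lower, Ccnd2 was 1.39-fold higher, and Stat5a had a ratio of 1.00 (0.957 to 1.05, untreated over estradiol). After scaling to pan-leukocyte genes these medians were 0.27 and 0.57 (log2) above 0, and both lists still stood apart. Inflammatory cytokine and NF-kB target genes did not stand apart, at percentile 92.7, with 7 of 26 higher and 7 lower: Ccl9 and Il1rn were 6.96-fold and 6.67-fold higher, and Cd83 and Tnf 11.5-fold and 5.71-fold lower.

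Genes of the estrogen-responsive list did not stand apart, at percentile 6.06, with 5 of 13 at least 2-fold higher and 4 at least 2-fold lower. Wisp2 (15.0-fold) and Cxcl12 (12.2-fold), which stromal cells also express, were highest, and Ltf (34.4-fold) and Pgr, the progesterone receptor gene (13.6-fold), were lowest. Stress lists stayed within the range of random lists. Unfolded protein genes lay at percentile 70.4, with 2 of 24 higher (Slc7a11 5.06-fold, Sesn2 3.24-fold) and 3 lower (among them Atf3 3.46-fold and Phgdh 2.94-fold). Heat shock and immediate early genes lay at percentile 40.2, with 6 of 22 higher (Bag3, from 891 to 8015, and Egr3, 5.93-fold, the highest) and 4 lower (Jund 3.91-fold the lowest). Cytoskeleton and migration genes lay at percentile 96.4, with 12 of 33 at least 2-fold higher and 10 at least 2-fold lower; Sell, the homing receptor L-selectin, was 9.38-fold and Fscn1 6.62-fold higher, and Ccr7, a chemokine receptor of lymphocytes, was 30.7-fold lower. Median and mean differed in sign for the macrophage, oxidase, glycolysis, estrogen-responsive and heat shock lists, none of which stood apart.

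The highest fold among genes with a mean of 50 or more was that of Capn13, a calpain protease, with 5 reads in untreated and 666 in estradiol cells, 129-fold higher (54.8 to 397). Apoc1, an apolipoprotein, followed with 2 and 147 reads, a ratio of 70.9 (19.3 to 591). The order of the highest folds depends on the pseudocount where reads are few: with 10 in place of 1, the log2 fold of Apoc1 went from 5.58 to 3.68, that of Capn13 from 6.75 to 5.46 and that of Aqp7 from 5.09 to 3.69, against 5.19 for Atp1a3. Aqp7 (42.2-fold), Aplnr (42.1-fold), Gpr84 (41.3-fold), Atp1a3 (38.1-fold), Rian (33.6-fold), Prkg2 (33.5-fold), Npnt (28.4-fold) and Tnc (27.2-fold) completed the 10 highest, among which Gpr84 is a receptor of myeloid cells and Npnt and Tnc are matrix proteins. Besides the basophil and neutrophil genes given above, the 10 lowest folds held Epx, eosinophil peroxidase (175 to 3 reads, ratio 60.5, 20.3 to 296), Cyp11a1 (48.0-fold, 21.8 to 132), Lrrc10b (118 to 2 reads, ratio 61.1, 16.6 to 511) and Ceacam10 (104 to 2 reads, ratio 53.9, 14.5 to 451).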

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

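No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The count of genes at least 2-fold higher (3324) ranged from 2698 to 4891 and that of lower genes (2283) from 1851 to 3313 over the pseudocounts, the filters, the 4 planned scalings and the requirement that the whole counting interval lie beyond 2-fold (2976 and 1954). With a threshold of 4-fold 1965 genes were higher and 894 lower, and with 1.5-fold 4284 were higher and 3700 lower. Scaling to the pan-leukocyte genes, chosen after seeing the data, gave 9606 higher and 563 lower, since it multiplies every estradiol value by 2.98. It turned 7 list medians that stood apart, to 0.902 for histone modifiers, 0.099 for G2 and M phase, 0.971 for ribosome biogenesis, 0.548 for cholesterol synthesis, 0.273 for interferon response, 0.574 for STAT5 targets and 0.021 for dendritic, mast and basophil markers, and the log2 folds of Serinc3 (0.321) and Tubb5 (0.443). All 7 lists still stood apart, because that scaling moves the random lists by about the same amount. With a minimum mean of 5 the median of replication-dependent histones was -0.384, as more low members then enter the list. Of 35 lists 21 stood apart. With that minimum the epithelial and histone lists no longer did, and with the mean of the members these lists, the myeloid transcription factors and the cell cycle inhibitors did not. Pluripotency and erythroid genes stood apart only with a minimum mean of 100, and stem and progenitor markers only with the mean of the members. With a pseudocount of 10 the log2 folds of 10 genes tried lay beyond their counting intervals and those of 35 within them. Depth limits the folds of genes with few reads in 1 library, such as Sox2 and Lin28a, whose counting intervals are wide.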

Other observations

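All tests of explanations given here were chosen after the results were seen.

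Adipocyte genes were higher in the estradiol library, in a list made after the data were seen that includes Apoc1 and Aqp7, named above for their folds. Of 17 measured members 12 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 8.10-fold higher, in a library where the stromal markers were 9.60-fold and the Y-linked genes 8.17-fold higher. Genes named from these 2 lists were chosen after their values were seen. Pparg, the master transcription factor of adipocytes, was 11.2-fold higher, Fabp4, a fatty acid carrier, 11.7-fold, Lpl, lipoprotein lipase, 8.64-fold, and Adipoq, adiponectin, 27.1-fold. Scd1, a fatty acid desaturase, was 18.9-fold lower. Imprinted genes, also listed after the data were seen and including Rian, one of the 10 highest folds, were at least 2-fold higher in 12 of 16 and lower in 2, with a median of 8.40-fold higher, beside the same stromal and Y-linked medians. Mest (26.7-fold), Dio3 (19.8-fold), Meg3 (17.3-fold), Dlk1 (11.8-fold) and H19 (11.4-fold) were among the higher ones, and Grb10 (8.45-fold) and Kcnq1ot1 (2.88-fold) were lower. Kcnq1ot1 is antisense to Kcnq1 and uncertain without a stated strand setting.

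Esr1, the estrogen receptor gene and a member of the estrogen-responsive list, chosen after its value was seen, had 6336 in the untreated and 3303 in the estradiol library, 1.92-fold lower (1.84 to 2.00).

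The first pattern is the higher level of stromal and matrix genes in the estradiol library. A candidate explanation is RNA from male stromal cells in a library otherwise mostly female: the 4 Y-linked genes had a median log2 fold of 3.03, close to the stromal median of 3.26, while Xist was 6.01-fold lower, and Fn1 and Bgn, abundant stromal transcripts, reached 829872 and 207359. The stated sort against feeder cells would remove such cells where it was applied, and a different sex of the donor animals in the 2 libraries is not excluded for the Y-linked genes and Xist. Induction of the stromal genes within the leukocytes cannot be told apart for the list. The interquartile range of its log2 folds, 0.458, was narrower than in most lists (median 1.45), but 4 of 29 other lists were narrower still. Those were the S phase, G2 and M phase, ribosomal protein and oxidative phosphorylation lists. A narrow spread is therefore not particular to RNA from a single outside source, and it decides nothing here. An effect of C/EBPα on these genes stays open and untested.

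The second pattern is the lower level of B cell identity genes. Dilution of leukocyte RNA by other RNA would lower all of them by 1 factor, and 2 estimates of that factor are the 6.01-fold of Xist and the 2.98-fold of the pan-leukocyte genes, whose lowest member, Ptpn22, was 7.50-fold lower. The list's median log2 fold of -3.49 (bootstrap 95% interval over genes -3.78 to -3.09) lay below the -2.59 of Xist, as did 22 of its 27 members, which argues against dilution as the whole cause. This rests on Xist and the pan-leukocyte genes keeping their level per leukocyte, which a different sex of the donor animals would break for Xist. The bootstrap over genes covers neither the error of these estimates nor variation between cultures. Much of the difference may still be dilution: the estimate from Xist is 6.01-fold, against the list's median of 11.2-fold lower. The estimate from the pan-leukocyte genes, 2.98-fold, is smaller. An effect of C/EBPα, the factor the design names, stays open as an untested hypothesis, as does a change in the kinds of leukocytes present.

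The third pattern is the split of granulocyte genes. Dilution of leukocyte RNA alone is argued against, since 12 of 26 members of the list had a counting interval wholly below the fold of Xist. That holds only if Xist kept its level per leukocyte, which a different sex of the donor animals would break. The intervals cover counting error only. Fewer neutrophils and basophils among the estradiol cells is a possible explanation for the lower part and was not tested separately, and the stated magnetic sort for CD19 would remove such cells where it was applied. Of the lower genes, the untreated library held S100a9 at 17340, Ngp at 11312 and the basophil gene Mcpt8 at 2419, beside Pax5 at 7546. The large folds of these genes thus start from a high untreated level. For the 8 granule and oxidase genes that were at least 2-fold higher, RNA from stromal cells cannot be told apart from expression in the leukocytes, because they were picked for being higher, so that their median log2 fold of 2.54 (range 1.87 to 3.73) decides nothing, and no library of stromal cells alone was used here. Induction by C/EBPα stays open for them.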
